A study of Rattus norvegicus with 12 samples.

How the data were processed

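Colon and hippocampus RNA of rats with hypoxic-ischemic brain damage and of sham controls was analysed in 4 groups of 3 libraries, taken from the titles and the treatment and tissue labels. Per the labels' protocols, total RNA was extracted with TRIzol, mRNA was purified and fragmented, and libraries were amplified by PCR. The aligner, the quantifier, the genome build and the annotation are not given in the sources used here.

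For each tissue the authors deposited 1 table with FPKM per library, per the file headers. The ratios of low values between libraries of a tissue showed no repeated steps of whole reads, so the depth of the libraries could not be recovered and no counting interval is given; only protein-coding genes were listed, and all genes but Tlr4 in the hippocampus had a mean of at least 0.5 FPKM in at least 1 group. In the deposited tables the log2 fold change was the difference of the group means of log2(FPKM + 1), within 1e-06 for 14803 of 14803 colon genes and 14265 of 14266 hippocampus genes, and the columns headed as group FPKM held those log2 means. The deposited fold change was the corresponding ratio. The exception in both was again Tlr4 in the hippocampus, where these 2 deposited values stood in each other's column (0.308 as the fold change and 1.24 as the log2 fold change); the reason is not known, and its FPKM values are used as deposited. The deposited p-value was unadjusted and equal, for every gene, to one side of a 2-sided comparison of mean FPKM that allows unequal variances, that is to its p divided by 2, so it never exceeded 0.500. It was used only to describe the authors' own calls.

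The colon header named 2 sham columns alike, so these were used as sham libraries without a number of their own. Gene symbols were taken from the deposited tables: 14620 colon and 14114 hippocampus symbols, of which 12984 and 12563 matched a symbol of the NCBI RefSeq annotation of the rat assembly GRCr8 and another 616 and 612 a synonym. For list members not listed under their own symbol, that table's synonyms were used. Where a symbol stood at several gene identifiers, the one with the highest mean FPKM was used.

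Before the data were examined, the samples of each group, the tests, the rule for named genes, 60 gene lists and the first set of alternatives were fixed. The plan had named a count model for tables of counts and, for FPKM, limma on log2(FPKM + 1); since the tables held FPKM, the latter was used. limma 3.58.1 in R 4.3.3 was run with eBayes and a mean-variance trend on the genes with at least 1 FPKM in at least 3 libraries, for the 6 libraries of each tissue, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A fold change is on the log2(FPKM + 1) scale and understates the change of low genes. The difference between the tissues was planned only for counts; it was fitted here with limma over the 12 libraries on genes in both tables with the same filter, and since the tables were made separately by the authors it compares changes within each table. Overlap of calls was tested with one-sided Fisher's exact tests per direction.

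Gene lists were tested with camera in limma with a preset correlation of 0.01 between genes, for lists with at least 5 tested members, with adjustment over the lists of a tissue. Of 42 lists meant for the colon 40 were tested, and of 44 for the hippocampus 39. For each list the number of members past an adjusted p of 0.05 over the list alone was set beside that over all genes tested. The rule for named genes took, per tissue, up to 8 called genes per direction with a mean of at least 1 FPKM, non-overlapping groups and no provisional name; where fewer than 3 passed in a direction, the 5 with the smallest p as values; 8 genes of the TLR4 pathway; up to 4 members with the smallest p of each list described; and the 5 leading genes of the interaction. Some genes that it took are not reported here. Errors of log2 changes are standard errors and errors of FPKM are SDs.

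Both tests were tried on simulated data with the means of the real libraries and, for each gene, the spread that limma fitted. In 5 runs with 200 changed genes among the 13753 of the colon, 58.5% of the genes changed 1.5-fold, 91.0% of those changed 2-fold and 99.1% of those changed 4-fold were called, and 6.29% of the calls were false. For the 13181 genes of the hippocampus these shares were 86.6%, 99.7%, 99.7% and 5.07%. The changed genes were drawn from those with a mean log2(FPKM + 1) over 2, so the shares do not hold for lower genes. The shares also rest on 200 changed genes per run. With fewer changed genes the adjusted threshold is stricter, and a smaller share of them would be called. The shares are therefore no estimate of how many real changes were found. A list of 25 genes shifted by 0.25 on the log2 scale was called in 10 of 10 runs in either tissue, and of 250 unshifted lists 0 were. The simulated genes varied independently of each other, so this says nothing of false calls for single genes or lists whose genes vary together. Other splits of the real colon libraries gave between 7 and 18 lists and between 0 and 311 genes.

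Alternatives were a pseudocount of 0.1, no filter on low values, a 2-fold minimum, 1 fit over the 12 libraries, the replicate number as a block in the hippocampus, an estimated correlation and fry for the lists, and leaving out each library in turn. Scaling by median ratios, quantile normalization, the Hox axis score as a covariate in the colon (with a preset and an estimated correlation for the lists) and the overlap without the libraries apart in genes of the Y chromosome were added after the data were seen, as were the 2 lists of Hox genes behind that score. Alternatives that need counts were not run.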

Results

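RNA was sequenced from the colon and the hippocampus of rats with hypoxic-ischemic brain damage (HI) and of sham controls, with 3 libraries in each of 4 groups and 12 in all. The title of the series concerns newborn rats, lipopolysaccharide released by gut bacteria, and signalling from the receptor TLR4 through the adaptor MyD88 to the transcription factor NF-κB. The comparisons therefore ask which genes differed between HI and sham in each tissue, and how the genes of that pathway behaved. Expression was given in FPKM (fragments per kilobase of transcript, scaled to the mapped total) for 14803 protein-coding genes in the colon and 14266 in the hippocampus, 13130 of them in both. Sequencing depth is unknown. The listed FPKM of a library summed to between 495505 and 509775 in the colon and to between 452291 and 466432 in the hippocampus. Between 13464 and 13726 genes reached 1 FPKM in a colon library, and between 13013 and 13210 in a hippocampus library. In the colon, 2 of the 3 sham libraries carried the same name and are called sham 3a and sham 3b. The labels do not say that each library came from a separate animal, so p-values measure the spread between libraries, which may be technical in part.

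Libraries of a group were not alike in genes of the Y chromosome. The 3 listed ones were at most at 0.202 FPKM in colon sham 1 and at least 10.6 FPKM in the other 5 colon libraries, whereas in the hippocampus they were at least 8.18 FPKM in HI 1 and at most 0.0959 FPKM in the other 5. The libraries of colon sham and of hippocampus HI thus did not all come from the same animals. In neither tissue were these genes balanced between HI and sham.

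In the colon, Mt-atp6, which codes for a subunit of the mitochondrial ATP synthase, fell from 8366 FPKM ± 692 (SD, n = 3) in sham to 1907 FPKM ± 124 (SD, n = 3) in HI, a log2 change of -2.13 ± 0.09 (SE; limma adjusted p = 0.000755). The histone gene H3f3c fell by 1.14 ± 0.08 on the log2 scale, from 152 FPKM ± 8.22 to 68.2 FPKM ± 4.99 (SD, n = 3 each; adjusted p = 0.00678). The ribosomal protein genes Rpl35al1 and Rpl35a fell by 1.32 ± 0.12 (adjusted p = 0.0342) and by 0.92 ± 0.09 (adjusted p = 0.0462). Of the genes with provisional names, named here after their values were seen, LOC100910669 rose from 0.0453 FPKM ± 0.0785 to 3.94 FPKM ± 0.398 (SD, n = 3 each; adjusted p = 0.00385) and AABR07027015.1 fell by 1.22 ± 0.12 (adjusted p = 0.0362). These 6 were the genes past an FDR of 0.05 among 13753 tested, 1 higher and 5 lower in HI. An unadjusted p under 0.05 was reached by 1533 genes, 632 higher and 901 lower, where 688 would be expected by chance. That count was 780 without sham 1, 678 without sham 3a and 1019 without HI 2, and up to 2221 (without HI 1). Among other splits of the 6 libraries, tried after the result was seen, sham 1, sham 3a and HI 1 against the rest gave 2525. The remaining splits gave between 159 and 889, so an excess over the number expected is not particular to HI. Rpl35a, Rpl35al1 and H3f3c belong to families with near-identical copies, whose reads the authors' counting could have split, so their values are uncertain. Whether the genes with provisional names have such copies is not known here. AABR07027015.1 varied together with Rpl35a and Rpl35al1 between hippocampus libraries, so the calls of these genes are not independent.

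Mt-atp6 lies on the mitochondrial genome from position 7919 to 8599 on the + strand, in the coordinates of the deposited file, whose genome build is not given in the sources used here. Its neighbour Mt-atp8 stood at 6357 FPKM ± 457 in sham and 5774 FPKM ± 500.0 in HI (SD, n = 3 each). The other 12 mitochondrial genes had a median log2 change of -0.07, between -0.24 and 0.01. Mt-atp6 was called whichever colon library was left out, with log2 changes from -2.20 to -2.09. H3f3c did not pass without sham 3a (adjusted p = 0.0648) or HI 3 (adjusted p = 0.0584). Rpl35al1 did not pass without sham 1, HI 2 or HI 3 (adjusted p = 0.130, 0.206 and 0.173). Rpl35a and AABR07027015.1 passed without sham 3b, but not without sham 1 (adjusted p = 0.300 and 0.224), sham 3a (0.118 and 0.133), HI 1 (0.0814 and 0.0712), HI 2 (0.237 and 0.0841) or HI 3 (0.102 and 0.102). Rpl35a did not pass with median-ratio scaling either (adjusted p = 0.0780). LOC100910669 was below the filter without any of the 3 HI libraries. The number of genes called was 3 without sham 1, 3 without sham 3a, 38 without sham 3b (28 higher and 10 lower), 13 without HI 1, 3 without HI 2 and 2 without HI 3. In 1 fit over the 12 libraries, which shares 1 estimate of the spread between the tissues, 24 colon genes passed. Of the 6 genes called before, 5 were tested there and 2 passed, Mt-atp6 (adjusted p = 4.41e-08) and H3f3c (0.0381). Among the others were Cdk1 (adjusted p = 0.0151), Fkbp5 (0.0151), RGD1562420 (0.0146), Anln (0.0146), Car9 (0.0381), Errfi1 (0.0381) and Gcnt2 (0.0407), whereas Rpl35a, Rpl35al1 and AABR07027015.1 did not pass (0.174, 0.195 and 0.201).

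**Figure D1:**
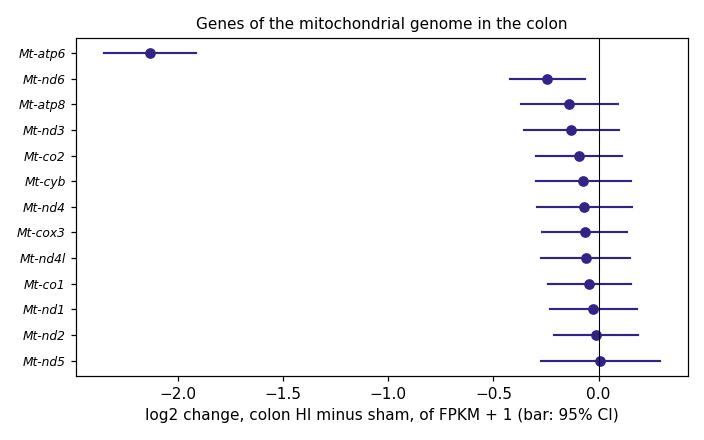
The log2 change of each gene of the mitochondrial genome in the colon, HI minus sham, on the x axis, with 95% confidence intervals from limma as bars (3 libraries per group). Mt-atp6 lies at -2.13 and the other 12 genes lie between -0.24 and 0.01.

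Genes of the cell cycle were lower together in the HI colon. All 29 tested members of the list were lower, with a median log2 change of -0.40 (camera adjusted p = 3.82e-16; adjusted p = 0.611 with an estimated correlation), and 19 fell when adjusted over the list alone. By limma over all genes tested, 0 of the list passed, while 1533 of all genes had an unadjusted p under 0.05. Cdc20, an activator of the anaphase-promoting complex, fell by 0.65 ± 0.08 from 30.5 FPKM ± 1.14 to 19.1 FPKM ± 1.09 (SD, n = 3 each). The mitotic kinase gene Cdk1 fell by 0.58 ± 0.07, Top2a, a topoisomerase of dividing cells, by 0.59 ± 0.10, and Ube2c, a ubiquitin-conjugating enzyme of mitosis, by 0.45 ± 0.08. The mean over the list was 0.31 to 0.44 below the sham mean in each HI library. Cdk1 passed over all genes without sham 3b (-0.63, adjusted p = 0.0496) and in 1 fit over the 12 libraries (0.0151). The list's call held whichever of the 6 libraries was left out (adjusted p up to 1.53e-09) and by fry (adjusted p = 0.0310). Markers of intestinal stem and progenitor cells did not pass by camera (adjusted p = 0.506, median -0.05) but were called lower by fry (adjusted p = 0.0209).

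**Figure D2:**
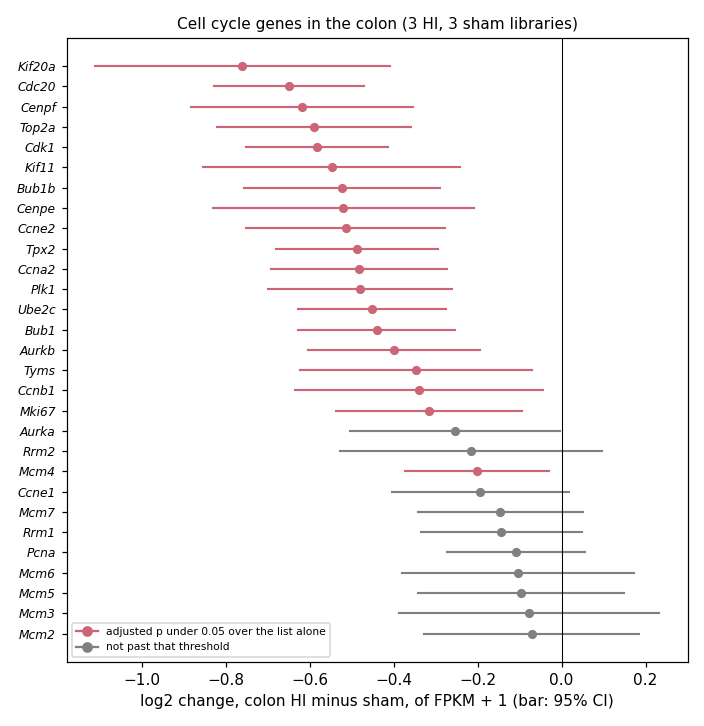
The log2 change of the 29 cell cycle genes in the colon, HI minus sham, on the x axis, with 95% confidence intervals from limma as bars (3 libraries per group). Every gene lies below 0, and the 19 that passed when adjusted over the list alone are in colour.

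Immediate early genes, which are transcribed within minutes of a stimulus, were higher in the HI colon (12 of 13 members, median 0.41, camera adjusted p = 3.21e-05; adjusted p = 0.620 with an estimated correlation). Adjusted over the list alone, 4 rose, and 0 did by limma over all genes. Fos, a subunit of the transcription factor AP-1, rose by 1.86 ± 0.45 from 9.85 FPKM ± 7.58 to 34.0 FPKM ± 11.2 (SD, n = 3 each). Dusp1, a phosphatase that inactivates MAP kinases, rose by 0.82 ± 0.23, Nr4a2 by 0.61 ± 0.15 and Zfp36, which promotes mRNA decay, by 0.41 ± 0.12. Without sham 3b, Fos passed over all genes too (2.39, adjusted p = 0.0472). The list's mean was 0.31 above the sham mean in sham 3b and 0.27 above it in HI 3. Genes of the hypoxia response and glycolysis were higher by a small margin (25 of 28, median 0.13, adjusted p = 0.000141; adjusted p = 0.742 with an estimated correlation, 0.0575 without HI 2). With a score of Hox genes for the place along the body axis as a covariate, the list's median was -0.02 (adjusted p = 0.582). Adjusted over that list alone only Car9, a carbonic anhydrase induced in hypoxia, rose, by 0.77 ± 0.09. Vegfa differed by 0.53 ± 0.24, Pkm by 0.37 ± 0.17 and Pdk1 by -0.28 ± 0.10. In the heat shock and unfolded protein response list (20 of 24 higher, median 0.11, adjusted p = 0.00338; adjusted p = 0.744 with an estimated correlation) the stress-induced transcription factor gene Atf3 rose by 1.52 ± 0.22 when adjusted over the list alone. Its level was 1.93 FPKM ± 0.597 in sham and 7.46 FPKM ± 2.02 in HI (SD, n = 3 each). Atf4, Trib3 and Ddit3 differed by 0.13 ± 0.06, 0.32 ± 0.18 and 0.19 ± 0.12, and the list's median was -0.02 without HI 2 (adjusted p = 0.814) and -0.06 with the Hox axis score as a covariate (adjusted p = 0.582).

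Clock genes were higher in the HI colon (11 of 16, median 0.20, adjusted p = 0.00571; adjusted p = 0.611 with an estimated correlation, 0.0667 without sham 1), with 0 members past the threshold either over all genes or adjusted over the list alone. Npas2 differed by 1.24 ± 0.34, Per1 by 0.44 ± 0.12 and Arntl by 0.44 ± 0.13. Of the glucocorticoid-responsive genes 10 of 14 were higher (median 0.19, adjusted p = 0.0104; adjusted p = 0.627 with an estimated correlation). Adjusted over the list alone, Errfi1, a feedback inhibitor of the EGF receptor, rose by 0.53 ± 0.10, and Dusp1 and Per1 rose as well. Fkbp5, a co-chaperone of the glucocorticoid receptor, fell by 0.84 ± 0.13 from 17.0 FPKM ± 0.931 to 9.13 FPKM ± 1.72 (SD, n = 3 each). None of these 4 passed by limma over all genes, except Errfi1 without sham 3b (0.63, adjusted p = 0.0477) and Errfi1 and Fkbp5 in 1 fit over the 12 libraries (0.0381 and 0.0151), and the list did not pass without sham 1 (adjusted p = 0.0667), sham 3a (0.0508) or HI 2 (0.0624), nor with the Hox axis score as a covariate (0.448), where the test pointed down.

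In the epithelium, genes of mucus and goblet cells were higher (13 of 15, median 0.30, adjusted p = 0.00337; adjusted p = 0.742 with an estimated correlation, 0.272 without HI 2). With the Hox axis score as a covariate their median was -0.05 (adjusted p = 0.339). Adjusted over the list alone, Clca1, a protein secreted by goblet cells, rose by 2.70 ± 0.77 and Atoh1, a transcription factor of secretory cells, by 0.30 ± 0.07, while B3gnt6, an enzyme of mucin glycosylation, fell by 0.50 ± 0.09. By limma over all genes 0 of them passed. Retnlb, a secreted goblet cell protein, differed by 2.37 ± 0.95. Libraries overlapped: Clca1 stood at 217 FPKM in sham 3b and 213 in HI 1, and Retnlb at 65.3 and 31.8 FPKM. Genes of tight and adherens junctions were higher too (14 of 19, median 0.13, adjusted p = 0.00571; adjusted p = 0.620 with an estimated correlation, 0.0575 without HI 2), with 0 members past the threshold over all genes or adjusted over the list alone. The claudin genes Cldn4 and Cldn3 differed by 0.95 ± 0.26 and 0.40 ± 0.14, and the tight junction gene Tjp3 by 0.22 ± 0.08.

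In the wall and vessels, smooth muscle genes were higher (9 of 10, median 0.12, adjusted p = 0.0104; adjusted p = 0.742 with an estimated correlation, 0.0756 without sham 3a and 0.204 without HI 3). With the Hox axis score as a covariate their median was -0.02 (adjusted p = 0.827). Lmod1 differed by 0.33 ± 0.09, Des by 0.39 ± 0.16, Synpo2 by 0.38 ± 0.17 and Myh11 by 0.11 ± 0.08. Pericyte markers were lower (8 of 10, median -0.25, adjusted p = 0.0292; adjusted p = 0.611 with an estimated correlation, 0.115 without HI 1 and 0.0624 without HI 2). Pdgfrb, the receptor for platelet-derived growth factor, differed by -0.35 ± 0.12, Cspg4 by -0.29 ± 0.10, Higd1b by -0.60 ± 0.26 and Abcc9 by -0.26 ± 0.12. Complement genes were higher (12 of 17, median 0.12, adjusted p = 0.0263; adjusted p = 0.627 with an estimated correlation, 0.210 without sham 3b, 0.138 without HI 3, 0.0665 with no filter on low values and 0.0553 with median-ratio scaling). C1s differed by 0.31 ± 0.09, Serping1, an inhibitor of C1, by 0.37 ± 0.13, and the complement regulators Cd59 and Cd55 by 0.98 ± 0.28 and 0.75 ± 0.25. Cd59 alone of these passed over all genes without sham 3b (1.31, adjusted p = 0.0477). In these 3 lists 0 members passed over all genes or adjusted over the list alone.

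Tlr4, the receptor for lipopolysaccharide (chromosome 5, 82587420 to 82601052, + strand), stood at 7.21 FPKM ± 5.42 in the sham colon and 13.7 FPKM ± 2.38 in HI (SD, n = 3 each), a log2 difference of 1.01 ± 0.40 that did not pass (limma adjusted p = 0.428). Its level was 3.82 FPKM in sham 1, 4.36 in sham 3a and 13.5 in sham 3b, against 10.9, 15.4 and 14.6 FPKM in HI 1, HI 2 and HI 3. Without sham 3b the difference was 1.51 and passed (adjusted p = 0.0472). Sham 3b was also the sham library with the highest Hox axis score (0.30, described below), so leaving it out widens that difference between the groups. The list of TLR4, MyD88 and NF-κB genes was higher by a small margin (17 of 26, median 0.06, mean 0.15, camera adjusted p = 0.00616; adjusted p = 0.611 with an estimated correlation). With 1 library left out its median lay between 0.03 and 0.10, and the camera adjusted p was up to 0.0485. Adjusted over the list alone, Irak2, a kinase that acts after MyD88, rose by 0.40 ± 0.08 from 14.1 FPKM ± 0.678 to 18.9 FPKM ± 0.971 (SD, n = 3 each), and 0 members passed by limma over all genes. Nfkb2 differed by 0.25 ± 0.07 and Lbp, which carries lipopolysaccharide to its receptor, by 1.15 ± 0.47. Myd88 differed by 0.11 ± 0.08, Rela by 0.05 ± 0.07, Nfkb1 by -0.01 ± 0.08, Nfkbia by 0.19 ± 0.11 and Il1b by -0.04 ± 0.29. Tnf, at 0.893 FPKM ± 0.258 in sham and 0.863 FPKM ± 0.0991 in HI (SD, n = 3 each), was below the filter, and Il6 was not among the listed genes.

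The colon libraries also differed in Hox genes, which are expressed in order along the body axis and were chosen after the data were seen. Hoxb13, of the most posterior group, was listed at 0 in sham 3a and stood at 0.466 FPKM in sham 1, 11.7 in sham 3b, 6.70 in HI 1, 41.4 in HI 2 and 63.0 in HI 3. Hoxb6 stood at 56.5, 49.1, 5.50, 20.5, 1.93 and 2.64 FPKM in the same libraries. A Hox axis score, the mean log2(FPKM + 1) of 3 group 13 Hox genes minus that of 21 Hox genes of groups 2 to 9, was -2.21, -2.71 and 0.30 in sham 1, 3a and 3b and -0.75, 1.58 and 2.03 in HI 1, 2 and 3. Its mean was 2.49 higher in HI, with an exact two-sided permutation p of 0.2 where 0.1 is the smallest that 3 against 3 libraries allow. Without sham 3b, both remaining sham libraries scored below every HI library. For genes that passed only without sham 3b, HI therefore cannot be told apart from the place along the body axis. At equal score, the HI difference of Tlr4 was 0.12 ± 0.30. With the score as a covariate, 698 genes had an unadjusted p under 0.05, Mt-atp6 alone passed, and the cell cycle median was -0.34 (adjusted p = 1.66e-16). The lists of hypoxia and glycolysis, heat shock, mucus and goblet cells, smooth muscle and glucocorticoid-responsive genes did not pass and pointed down (adjusted p from 0.339 to 0.827), the last with a median of 0.05. Complement did not pass either (0.17, adjusted p = 0.0805), and the other 6 lists called in the colon did. Another 9 lists passed at equal score and not without it, while 0 of the 40 lists passed there by camera with an estimated correlation (lowest adjusted p = 0.522, 2 at an unadjusted p under 0.05). Markers of fibroblasts (median -0.31, adjusted p = 0.000166), endothelial cells (-0.29, 1.31e-05) and erythroid cells (-0.45, 0.0259) were lower there, as were genes of the extracellular matrix (-0.29, 1.53e-07) and of oxidative phosphorylation (-0.07, 0.0125). Markers of B and plasma cells (1.11, 4.82e-06), T and NK cells (0.45, 0.00247) and absorptive colonocytes (0.37, 0.00103) and interferon-stimulated genes (0.15, 0.0329) were higher.

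**Figure D3:**
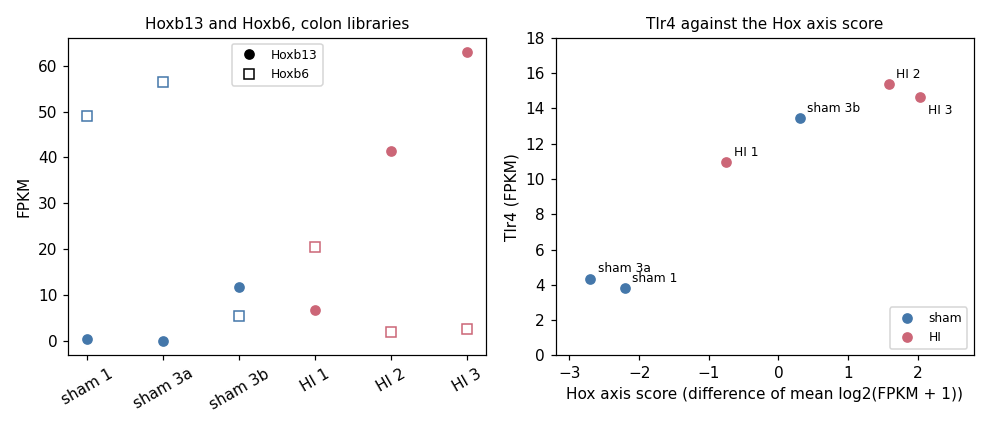
Left, FPKM of Hoxb13 (filled circles) and Hoxb6 (open squares) in each colon library; right, Tlr4 in FPKM against the Hox axis score of the 6 libraries, sham in blue and HI in red. Sham 3b, with a score of 0.30, has 13.5 FPKM of Tlr4, inside the HI range of 10.9 to 15.4 FPKM.

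Among single colon genes the smallest unadjusted p-values of the higher genes without a call belonged to Plekhh1 (0.91 ± 0.10, adjusted p = 0.0671), Car9, Atf3, the branching glycosyltransferase gene Gcnt2 (0.60 ± 0.09, adjusted p = 0.174) and the carboxylesterase gene Ces1f (0.90 ± 0.14, adjusted p = 0.182). Plekhh1 passed without sham 3b (0.97, adjusted p = 0.0472). Of 40 lists tested in the colon, 12 passed, 10 higher and 2 lower, and the other 28 had adjusted p-values from 0.115 to 0.983. Among these 12, list means of HI and sham libraries overlapped for immediate early, hypoxia and glycolysis, heat shock and glucocorticoid-responsive genes. They also overlapped for mucus and goblet cells, junctions, smooth muscle and complement, but not for the cell cycle, clock, pericyte and TLR4 lists. Without HI 2, 6 lists passed. With an estimated correlation 0 of the 40 passed by camera, 1 had an unadjusted p under 0.05, and fry called 3, those of the cell cycle, pericytes and stem and progenitor cells. Lists of cytokines and chemokines (adjusted p = 0.727), the inflammasome (0.580), interferon-stimulated genes (0.774), macrophages (0.827) and neutrophils (0.550) were among those that did not pass. For cytokines and chemokines and for interferon-stimulated genes the medians (-0.05 and -0.04) and means (-0.0032 and -0.05) lay below 0 while the test pointed up, and for the inflammasome the median of -0.04 did while the mean of 0.01 and the test pointed up. The authors' deposited table gave 2000 colon genes a p-value under 0.05, 698 higher and 1302 lower, and 49 of them changed at least 2-fold. By chance 1480 would be expected, since the deposited p-value is 1-sided.

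In the hippocampus, genes that respond to glucocorticoids were higher in HI. All 15 tested members were higher, with a median log2 change of 0.25 (camera adjusted p = 9.49e-10; adjusted p = 0.0796 with an estimated correlation), and 8 rose when adjusted over the list alone. By limma over all genes 0 of them passed, while 872 of all genes had an unadjusted p under 0.05. The sulfotransferase gene Sult1a1 rose by 0.95 ± 0.13 from 4.32 FPKM ± 0.936 to 9.17 FPKM ± 0.851 (SD, n = 3 each). The metallothionein gene Mt2A rose by 0.85 ± 0.15 from 44.3 FPKM ± 7.94 to 80.6 FPKM ± 14.5, Fkbp5 by 0.31 ± 0.07 from 13.7 FPKM ± 0.255 to 17.2 FPKM ± 1.29, and Dusp1 by 0.27 ± 0.07. The list held whichever of the 6 libraries was left out (adjusted p up to 2.31e-06) and by fry (adjusted p = 0.0112). Immediate early genes were higher as well (15 of 19, median 0.18, adjusted p = 1.40e-05; adjusted p = 0.288 with an estimated correlation), and 7 rose adjusted over the list alone, 0 by limma over all genes. The transcription factor gene Egr1 rose by 0.41 ± 0.08, Arc, a regulator of synaptic strength, by 0.50 ± 0.12 from 28.9 FPKM ± 2.55 to 41.6 FPKM ± 6.92 (SD, n = 3 each). Nr4a1 rose by 0.35 ± 0.08 and Btg2 by 0.34 ± 0.09. Dusp1 belongs to both lists.

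**Figure D4:**
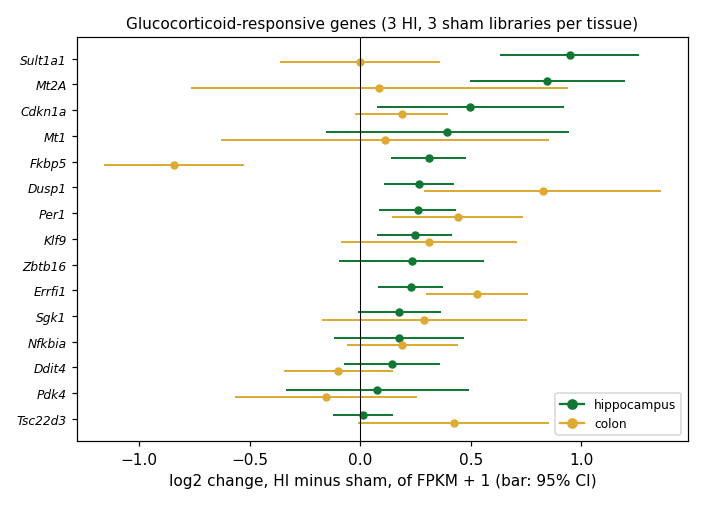
The log2 change of each glucocorticoid-responsive gene, HI minus sham, on the x axis in the hippocampus (green) and the colon (yellow), with 95% confidence intervals from limma as bars (3 libraries per group and tissue). All 15 genes lie above 0 in the hippocampus, and Fkbp5 lies at 0.31 there and at -0.84 in the colon.

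Genes of the extracellular matrix were lower in the HI hippocampus (18 of 22, median -0.11, adjusted p = 0.00743; adjusted p = 0.288 with an estimated correlation). Adjusted over the list alone 3 fell, the collagen gene Col3a1 by 0.54 ± 0.10 from 18.3 FPKM ± 0.615 to 12.3 FPKM ± 1.84 (SD, n = 3 each) and the proteoglycan genes Lum by 0.43 ± 0.10 and Dcn by 0.38 ± 0.10. The matrix glycoprotein gene Thbs1 rose by 0.71 ± 0.16, and 0 of these passed by limma over all genes. Lum and Dcn are also in the list of meningeal markers, which did not pass (adjusted p = 0.316). Ependymal cell markers were higher (5 of 6, median 0.50, adjusted p = 0.00406; adjusted p = 0.310 with an estimated correlation). The cilium genes Rsph1 and Dynlrb2 rose by 0.48 ± 0.14 and 0.69 ± 0.21 adjusted over the list alone, 0 over all genes by limma. Cfap126 differed by 1.24 ± 0.46 and Tmem212 by 0.51 ± 0.23. Genes of the choroid plexus, the tissue in the ventricles that makes cerebrospinal fluid, were abundant in HI 1 alone. Ttr stood at 4177 FPKM there and at most at 18.2 FPKM in the other 5 libraries, and Folr1 at 57.4 against at most 2.76 FPKM. Without HI 1 the ependymal, matrix, glucocorticoid and immediate early lists still passed.

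All 14 myelin genes were higher in the HI hippocampus (median 0.51, adjusted p = 0.000209; adjusted p = 0.925 with an estimated correlation, 0.0528 without HI 1), but libraries overlapped. Relative to the sham mean the list's mean was -0.21, -0.34 and 0.55 in sham 1, 2 and 3 and 0.95, -0.13 and 0.71 in HI 1, 2 and 3. Mal differed by 0.98 ± 0.45, Ermn by 0.66 ± 0.36, Cldn11 by 0.51 ± 0.30 and Mbp, a main protein of the sheath, by 0.43 ± 0.25, and 0 members passed over all genes or adjusted over the list alone. Markers of oligodendrocyte precursors were higher (9 of 9, median 0.19, adjusted p = 0.0220; adjusted p = 0.925 with an estimated correlation): the transcription factor genes Olig2, Sox10 and Olig1 differed by 0.26 ± 0.07, 0.29 ± 0.12 and 0.19 ± 0.13, and Bcas1 by 0.20 ± 0.15. That list did not pass without sham 1 (adjusted p = 0.168), sham 2 (0.0854), HI 1 (0.248) or HI 3 (0.0599).

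Another 4 lists passed in the hippocampus with the same adjusted p = 0.0220 and with medians under 0.1 in size, and none of them passed with an estimated correlation (adjusted p = 0.453 for clock genes and 0.925 for the others). Clock genes were higher (13 of 16, median 0.09), with Per1 at 0.26 ± 0.07, Per2 at 0.16 ± 0.07, Bhlhe40 at 0.18 ± 0.08 and Dbp at 0.09 ± 0.06. Complement genes were higher (11 of 13, median 0.08), with C1qc at 0.34 ± 0.09, C1qa at 0.16 ± 0.07, C1s at 0.20 ± 0.11 and Cd55 at 0.17 ± 0.13. Presynaptic genes were lower (15 of 19, median -0.07), with Syn2, a synapsin, at -0.24 ± 0.08, Stx1a at -0.28 ± 0.12, Cplx1 at -0.16 ± 0.06 and Syp at -0.12 ± 0.06. Genes of oxidative phosphorylation were lower (26 of 35, median -0.05), with Cyc1 at -0.20 ± 0.07, Ndufs8 at -0.18 ± 0.07, Uqcrc1 at -0.18 ± 0.08 and Atp5b at -0.12 ± 0.06. In these 4 lists 0 members passed over all genes or adjusted over the list alone, by limma, and each was lost without at least 3 of the 6 libraries. Clock genes did not pass without sham 1, sham 3, HI 1 or HI 3 (adjusted p = 0.0514, 0.140, 0.0698 and 0.0599), nor complement without sham 1, sham 2 or HI 1 (0.0786, 0.0733 and 0.537). Presynaptic genes did not pass without sham 1, sham 2, HI 1 or HI 2 (0.258, 0.131, 0.177 and 0.0985) and oxidative phosphorylation without sham 3, HI 1 or HI 3 (0.403, 0.741 and 0.0593). With quantile normalization oxidative phosphorylation (median -0.03, adjusted p = 0.453) and presynaptic genes (0.131) did not pass, and with no filter on low values complement did not (0.0776).

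Genes of the TLR4 pathway showed no call in the hippocampus. Tlr4 itself, at 0.196 FPKM ± 0.0861 in sham and 0.486 FPKM ± 0.191 in HI (SD, n = 3 each), was below the filter, and Il1b, Il6 and Tnf were not among the listed genes. Of the 14266 genes in the authors' deposited table for the hippocampus, Tlr4 was the only one with means under 0.5 FPKM in both groups, and the only one with fold change and log2 fold change in each other's column. The list did not pass (22 members, median 0.02, adjusted p = 0.575): Chuk differed by 0.25 ± 0.09, Irak3 by 0.24 ± 0.13, Irak4 by -0.20 ± 0.14, Nfkbia by 0.18 ± 0.13, Myd88 by -0.07 ± 0.13, Nfkb1 by -0.04 ± 0.09 and Rela by -0.03 ± 0.10. Lists of microglia (adjusted p = 0.924), disease-associated microglia (0.618), reactive astrocytes (0.924), cytokines and chemokines (0.899), apoptosis (0.687) and excitatory neurons (0.801) did not pass either. The median lay below 0 and the mean above it for cytokines and chemokines (-0.06 and 0.03), disease-associated microglia (-0.02 and 0.01) and reactive astrocytes (-0.02 and 0.00), where the test pointed up, down and up.

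One gene passed over all genes in the hippocampus, Rn60_20_0051.7, which has a provisional name and is named after its values were seen. It fell by 2.81 ± 0.23 from 7.12 FPKM ± 2.40 to 0.139 FPKM ± 0.240 (SD, n = 3 each; limma adjusted p = 0.0198). Without sham 1, sham 2 or sham 3 it was below the filter, and the call was lost with a pseudocount of 0.1 (adjusted p = 0.134) and in 1 fit over the 12 libraries (adjusted p = 0.581), where Usp54 was the gene called (adjusted p = 0.0123). The number of genes called was 3 without sham 1, 0 without sham 2 and 0 without sham 3 by limma (529 and 881 at an unadjusted p under 0.05), 3 without HI 1, 3 without HI 2 and 5 without HI 3. Of 13181 genes tested, 872 had an unadjusted p under 0.05, 455 higher and 417 lower, where 659 would be expected by chance. That count was 581 without sham 1, 529 without sham 2 and 1628 without HI 2. Among other splits of the 6 libraries, tried after the result was seen, sham 1, sham 2 and HI 2 against the rest gave 1359. The remaining splits gave between 236 and 753, so an excess over the number expected is not particular to HI. The genes with the smallest p-values that did not pass were, among the higher ones, Usp54 (0.61 ± 0.07, adjusted p = 0.124), Sult1a1, the prostaglandin transporter gene Slco2a1 (0.64 ± 0.10, adjusted p = 0.536), Mt2A and Pnpla7 (0.50 ± 0.09). Among the lower ones they were the potassium channel subunit gene Kcne5 (-0.73 ± 0.09, adjusted p = 0.140), Cmc2 (-0.62 ± 0.10), the elastin gene Eln (-1.07 ± 0.19, adjusted p = 0.599), Col3a1 and the amino acid transporter gene Slc38a5 (-0.55 ± 0.11). Of 39 lists tested, 10 passed, 7 higher and 3 lower, and 29 had adjusted p-values from 0.180 to 0.999. Among these 10, list means of HI and sham libraries overlapped for myelin, oligodendrocyte precursor, complement, presynaptic and oxidative phosphorylation genes. Without sham 1, 6 lists passed, and 6 without HI 1. With an estimated correlation 0 passed by camera, 4 had an unadjusted p under 0.05, and fry called 1. The authors' deposited table gave 1453 hippocampus genes a p-value under 0.05, 709 higher and 744 lower, against 1427 expected by chance, and 3 of them changed at least 2-fold.

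Whether the response differed between the tissues was tested over all 12 libraries. Since genes of the Y chromosome were near 0 in 5 of 6 hippocampus and 1 of 6 colon libraries, the tissue can be separated from that difference only in part. The change of Mt-atp6 in the colon minus that in the hippocampus was -2.28 ± 0.11 on the log2 scale (limma adjusted p = 1.19e-06). In the hippocampus the gene stood between 8942 and 10036 FPKM in sham and between 10133 and 10774 FPKM in HI. Fkbp5, lower in the HI colon and higher in the HI hippocampus, had a difference of -1.15 ± 0.15 (adjusted p = 0.0464; 0.0505 with a pseudocount of 0.1 and 0.0611 with quantile normalization). These 2 were the genes past the threshold among 13015 tested, and 1198 had an unadjusted p under 0.05, where 651 would be expected by chance. That count was 758 without colon sham 3a and 1933 without colon HI 1. The next genes were Usp54 (-0.61 ± 0.10, adjusted p = 0.146), the cytokinesis gene Anln (-0.84 ± 0.15, adjusted p = 0.256) and the protease gene Htra1 (-0.87 ± 0.15, adjusted p = 0.256), and the difference for Tlr4 was 0.70 ± 0.45 (adjusted p = 0.624). Usp54 and Anln passed without colon sham 3b (-0.63, adjusted p = 0.0431, and -0.90, adjusted p = 0.0482) and Htra1 without hippocampus sham 3 (-1.02, adjusted p = 0.0133). Leaving out single libraries ended the Fkbp5 call, with adjusted p-values of 0.103 without colon sham 1, 0.151 without colon sham 3a, 0.0748 without colon HI 1, 0.0946, 0.232 and 0.113 without hippocampus sham 1, 2 and 3, and 0.0675, 0.208 and 0.184 without hippocampus HI 1, 2 and 3. The number of genes called was 25 without colon sham 3b and 1 without colon sham 1, colon sham 3a, hippocampus sham 2, HI 2 or HI 3.

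By limma 0 genes passed the FDR threshold in both tissues. At an unadjusted p under 0.05, 30 genes were higher in both, against 14.1 expected from the 445 colon and 377 hippocampus genes among 11861 tested in both (Fisher's exact test, one-sided, p = 8.45e-05), and 35 were lower in both, against 22.8 expected (p = 0.00763). Without colon sham 1 and hippocampus HI 1, the libraries apart in genes of the Y chromosome, 13 were higher in both against 4.96 expected (Fisher's exact test, one-sided, p = 0.00146) and 19 lower against 9.25 (p = 0.00243). Fisher's test takes genes as independent, which they are not, so these p-values overstate the evidence. Of 100 splits of the libraries, the real one included, 4 shared at least the 65 genes found here, and another shared 111. H3f3c, called in the colon, was among the genes lower in both (-0.58 ± 0.21 in the hippocampus, limma adjusted p = 0.720). Its change there was -0.86 without HI 2 (limma adjusted p = 0.00991). HI 2 stood at 57.4 FPKM, within the sham range of 56.0 to 59.3 FPKM. Other shared genes, named after their values were seen and past the FDR threshold in neither tissue, included RGD1562420 (0.95 ± 0.10 in the colon and 0.77 ± 0.11 in the hippocampus), Ash1l, a histone methyltransferase (0.78 ± 0.13 and 0.64 ± 0.17), Errfi1 (0.53 ± 0.10 and 0.23 ± 0.06), Dusp1 (0.82 ± 0.23 and 0.27 ± 0.07), Per1 (0.44 ± 0.12 and 0.26 ± 0.07) and Thbs1 (0.73 ± 0.22 and 0.71 ± 0.16) among the higher ones. RGD1562420 passed in the colon without sham 3b (0.98, adjusted p = 0.0477) and with median-ratio scaling (adjusted p = 0.0351), and in the hippocampus without HI 3 (0.89, adjusted p = 0.0406). Among the lower ones were Eln (-0.70 ± 0.14 and -1.07 ± 0.19) and Lum (-0.40 ± 0.11 and -0.43 ± 0.10). Across all genes tested in both tissues, which are not independent replicates, the log2 changes had a correlation of 0.0158.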

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

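Tests on other splits of the single-gene calls, and all tests on the Hox axis score, stem cell markers, mitochondrial genes and gene copies, were chosen only after the result was seen.

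The response to HI differed between the tissues for Mt-atp6, by -2.28 ± 0.11 on the log2 scale, and for Fkbp5, by -1.15 ± 0.15, colon minus hippocampus, by limma over the 12 libraries. Genes of the Y chromosome were near 0 in 5 of 6 hippocampus libraries and in 1 of 6 colon libraries. The tissue can thus be separated from that difference between libraries only in part. The Fkbp5 call was lost in 9 of the 12 fits with 1 library left out (adjusted p up to 0.232), with a pseudocount of 0.1 (0.0505) and with quantile normalization (0.0611). Of 100 splits of the libraries, the real one included, 16 gave at least 2 genes, with up to 137 in the others, so chance is not excluded for the count.

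Tlr4 stood higher in the HI colon by 1.01 ± 0.40, and its level followed the Hox axis score across the 6 colon libraries (Pearson r = 0.930, exact permutation p = 0.00556; Spearman rho = 0.886, exact permutation p = 0.0333; 1 relation tested). Without sham 3a and HI 3, which lie farthest out, r was 0.920. At equal score the HI difference was 0.12 ± 0.30, so the place along the colon that the tissue came from is a candidate explanation. An effect of HI itself stays open: sham 3b, at 13.5 FPKM, lay inside the HI range of 10.9 to 15.4 FPKM, and with 3 libraries per group the score and HI can be separated only in part. Of the 10 splits of the colon libraries 2 gave at least the 6 genes called, and the split that set sham 1, sham 3a and HI 1 apart, along the Hox axis, gave 311, which points to a structure of these samples; 10 splits are too few for a share under 0.05.

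Cell cycle genes were lower in every HI colon library, and the real split had the largest median of 10 splits, 0.40 in size against at most 0.21 (1 of 10), which are too few for a share under 0.05. The place along the colon is argued against as the whole cause, since the median was -0.34 at equal Hox axis score against -0.40 before; by camera the list passed there at the preset correlation (adjusted p = 1.66e-16) but, as without the score (0.611), not at an estimated one (0.522). At that score markers of fibroblasts (-0.31), endothelial cells (-0.29), B and plasma cells (1.11) and T and NK cells (0.45) passed as well at the preset correlation, so a different make-up of the tissue stays open. A loss of stem and progenitor cells as large as the fall of the cell cycle genes is argued against by their markers, with a mean log2 change of -0.068 ± 0.087 (SE). That SE does not measure the spread between libraries, which was smaller. Relative to the sham mean, the list's mean was -0.021, -0.004 and 0.025 in sham 1, 3a and 3b. It was -0.070, -0.097 and -0.038 in HI 1, 2 and 3, each below every sham library. The list was also called lower by fry (adjusted p = 0.0209), so a smaller loss stays open. An effect of HI and the timing of the samples stay open and were not tested.

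Single genes called in 1 tissue may reflect differences between animals in near-identical copies or sequence variants: of 6 such genes with values in the other tissue, 5 were among the 5% with the highest spread within its groups. Rpl35a, Rpl35al1 and AABR07027015.1 varied together and are not independent. H3f3c was also lower in the HI hippocampus (-0.58 ± 0.21), at 30.4 and 32.4 FPKM in HI 1 and HI 3. HI 2, at 57.4 FPKM, lay in the sham range of 56.0 to 59.3 FPKM. The call without HI 2 (limma adjusted p = 0.00991) leaves out that library. Both an effect of HI and a difference between animals stay open for H3f3c. Mt-atp6 was the exception, at percentile 19.9. Fewer mitochondrial transcripts are argued against for it, since the other 12 mitochondrial genes had a median of -0.068. Among listed genes the largest rise, 1000.2 FPKM for Txn1, was below the 6459 FPKM that Mt-atp6 lost. FPKM is scaled to gene length, however, and neither gene lengths nor unlisted genes were analysed here. Reads assigned to another gene therefore cannot be told apart from a loss of transcript.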

How the results depend on the processing

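Scaling by median ratios, quantile normalization, the Hox axis score as a covariate with a preset or an estimated correlation, a pseudocount of 0.1 for the lists and for the tissue difference, no filter for the lists, and the overlap at an unadjusted p, with all libraries or without those apart in genes of the Y chromosome, were tests chosen only after the result was seen.

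Of the alternatives, 1389 of 1452 values for single genes and 213 of 311 for lists kept their direction and side of the threshold, and 39 of 72 counts of calls stayed within 1.5 times. Of the single genes 34 lost a call, 13 gained one and 16 turned, of the lists 87 lost a call and 11 turned, and of the counts 23 were lower and 10 higher. A call could be lost only by the 6 colon, 1 hippocampus and 2 tissue difference genes that had one. Most values for single genes belonged to genes without a call, which kept their side by staying uncalled. The share kept for single genes therefore says little about how firm the calls are. The colon gene count of 6 was 24 in 1 fit over 12 libraries (2 of the 6 among them), 1 with the Hox axis score as a covariate, and between 2 (without HI 3) and 38 (without sham 3b) with a library left out. The colon list count of 12 was 0 with an estimated correlation, with or without the Hox axis score, 3 by fry, and between 6 (without HI 2) and 14 (without sham 3b). The hippocampus gene count of 1 was 1 in 1 fit over 12 libraries, for another gene (Usp54), 0 with a pseudocount of 0.1 and between 0 (without sham 2 or sham 3) and 5 (without HI 3). The hippocampus list count of 10 was 0 with an estimated correlation, 1 by fry, and between 6 (without sham 1 or HI 1) and 11 (without HI 2). The tissue difference count of 2 was 1 with a pseudocount of 0.1 and between 1 (such as without colon sham 1) and 25 (without colon sham 3b). The overlap of 0 was 65 at an unadjusted p under 0.05, and 32 without colon sham 1 and hippocampus HI 1. The counts of 0 are by limma or camera. Fewer samples were fitted with a library left out; otherwise the cause was not tested.

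Some directions turned. In the colon, Nfkb1 was 0.029 with median ratios and 0.021 with the Hox axis score, and from -0.054 (without sham 3a) to 0.031 (without HI 3). Il1b in the colon was 0.00055, 0.031 and 0.41 with median ratios, quantile normalization and the Hox axis score, and from -0.35 (without sham 3b) to 0.22 (without sham 1). With that score Pkm, at 0.37 without it, was -0.039, and the list medians, between 0.11 and 0.30 without it, were -0.020 for hypoxia and glycolysis, -0.055 for heat shock, 0.045 for glucocorticoid-responsive genes with the test reversed, -0.047 for mucus and -0.024 for smooth muscle. In the hippocampus, Myd88 went from -0.19 (without sham 2) to 0.0030 (without sham 1), Nfkb1 from -0.11 (without HI 1) to 0.0065 (without HI 2), and Rela from -0.11 (without sham 1) to 0.040 (without sham 3). For the TLR4 list there the test turned down without HI 1, with medians from 0.0035 (without HI 1) to 0.039 (without HI 3). The cause was not tested.

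With the replicate number as a block in the hippocampus, 0 genes passed by limma (894 at an unadjusted p under 0.05; Rn60_20_0051.7 at an adjusted p of 0.315) and 10 lists did, with no other call changed. Libraries with the same number had correlations of -0.05, 0.08 and -0.03, and not every library correlated best with its own number, so the numbers were not taken as pairs. No paired analysis was possible because 2 colon sham libraries share a name, for the colon and the tissue difference. Alternatives on counts (size factors, total count scaling, a second count tool and voom) were not run, as the values are FPKM, and depth limits could not be set.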

Other observations

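The tests on other splits of the hippocampus gene count, the overlap without 2 libraries, and the genes described next, were chosen only after the result was seen.

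Other genes of the colon differed widely between libraries of a group. Mptx1 stood at 0.429, 6.65 and 7.15 FPKM in sham 1, 3a and 3b and at 20.9, 731 and 1162 FPKM in HI 1, 2 and 3. The transporter gene Slc5a8 stood at 0.235, 0.0968, 13.8, 10.7, 27.2 and 24.6 FPKM in the same order, and the chemokine gene Ccl25 at 91.8, 88.1, 15.0, 50.9, 1.93 and 1.95 FPKM. Reg3b, an antimicrobial lectin, stood at 95.4, 58.4, 4.01, 23.2 and 0.953 FPKM and was listed at 0 in HI 3. Slc5a8 was lowest, and Ccl25 and Reg3b highest, in sham 1 and 3a, the libraries with the lowest Hox axis scores. Whether these genes follow the score was not tested. In lists that did not pass, 14 colon genes (5 higher, 9 lower) and 7 hippocampus genes (3 higher, 4 lower) passed adjusted over the list alone. Among them, in the colon Il18 rose by 0.79 ± 0.18 and the neuropeptide gene Vip fell by 0.78 ± 0.16, and in the hippocampus the neuropeptide gene Cck fell by 0.38 ± 0.10 and the gap junction gene Gja1 rose by 0.23 ± 0.05. None of these 4 passed by limma over all genes, except Vip in 1 fit over the 12 libraries (adjusted p = 0.0415).

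Of the 10 splits of the libraries, 5 gave at least the 12 colon lists called, with up to 18 in the others, and 1, the real split, gave the 10 hippocampus lists, against at most 8. For the hippocampus gene count of 1, 8 of 10 splits gave as many, with up to 26. These splits are too few for a share under 0.05. For the 65 genes shared between tissues at an unadjusted p under 0.05, 4 of 100 splits, the real one included, gave as many, with up to 111 in the others. The others were drawn at random from a larger number of splits. The threshold of that overlap was also chosen after the result was seen, so a share this near 0.05 does not exclude chance. The log2 changes of all genes tested in both tissues, which are not independent replicates, had a correlation of 0.0158. The reason for the overlap stays open. Transcripts of the Y chromosome were absent or near 0 in colon sham 1 and in all hippocampus libraries but HI 1, so if each library came from 1 animal, at most 1 sham and 1 HI animal can have given libraries to both tissues. Without these 2 libraries 32 genes were shared, 13 higher against 4.96 expected and 19 lower against 9.25.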
